A study of Escherichia coli with 81 samples.

How the data were processed

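Each slide was a spotted 2-colour array of *E. coli* genes on which a time-course sample and a reference sample, harvested from the same strain before the shift to acetate, were hybridised together. Per the labels, the deposited value of a spot is a log ratio of the reference over the time-course sample. Its sign was turned here, so that a positive value means a higher level after the shift. The base of the logarithm, the scanner, the background correction, the normalization and the filter on spots are not given in the sources used here. The design written before the data were examined assumed log2 values; the same tests were kept, because they do not depend on the base, and values are given in deposited log units. Values ran from -2.109 to 2.137. Slide medians lay between -0.112 and 0.109, and each slide was centred on its own median. A ratio within an array shows a change relative to the other genes of the slide, not an absolute one. No signal intensities or background values were analysed here, so the precision of a spot is known only from its pair: spots of a gene differed by a median SD of 0.02 to 0.04 across the 4 print layouts.

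The slides carry 4 print layouts, called A to D here, with 16, 23, 24 and 18 slides. Gene names were taken from the platform annotation and checked against the gene table of the K-12 MG1655 assembly. Of 8640 to 9600 spots per layout, 6392 name 1 gene, 48 name several and 2200 to 3160 name none; 4 of the named ones per layout were not found in the table. Only spots with 1 gene were used, and the 2 spots of each of the 3196 genes were averaged. A replicate is the number in brackets in the sample title, and its slides 1 and 2, which carry the same genes, were averaged into 1 set of values. Print layout goes with time and replicate number: all samples of the first 30 min are on layout D, and replicates 1, 2 and 3 at 1 to 4 h are on layouts A, B and C. At 1 to 4 h the time-course sample was in Cy5 in replicate 3 and in Cy3 in the others.

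On 11 slides, those of wild-type replicate 2 at 1 to 6 h on layout B, the values did not go with the gene names. Their median correlation across genes with the other slides lay between -0.029 and 0.0165, against 0.299 to 0.653 for the 70 other slides. These 6 replicates were therefore left out of the gene comparisons, which departs from the design, and a fit that includes them is an alternative. Since it adds values that do not go with their gene names, that fit cannot check the result of a gene.

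The fit held 35 replicates, 18 group means and a term for the dye of the time-course sample, with 16 residual degrees of freedom for a gene measured in every replicate. It was made by least squares per gene with missing values left out, and the spread was moderated with limma 3.58.1 in R 4.3.3 (squeezeVar, 4.258 prior degrees of freedom, prior SD 0.092). Estimates were checked against limma's own fit on genes without missing values. For 608 genes the dye term could not be estimated and was left out. Group means were averaged over the early (5, 15 and 30 min), middle (1 and 2 h) and late (3 to 6 h) phases and tested against 0 in each strain and between the strains, 9 contrasts in all. A gene was tested where it was measured at every time point of the phase in the strains compared. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. The spread of the reference sample is not part of the test against 0.

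Gene lists fixed before the data were examined were tested with limma's cameraPR on the moderated t, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over all 212 tests of 24 lists. The lists were acetate uptake and glyoxylate shunt, gluconeogenesis, TCA cycle, glycolysis, pentose phosphate and Entner-Doudoroff, PTS sugar uptake, CRP-activated uptake and catabolism of other carbon sources, fatty acid degradation, aerobic respiratory chain, ATP synthase, fermentation and anaerobic respiration, ribosomal proteins, translation factors and RNA polymerase core, aminoacyl-tRNA synthetases, amino acid biosynthesis, purine and pyrimidine biosynthesis, iron acquisition, RpoS-dependent general stress, acid resistance, oxidative stress defence, heat shock, flagella and chemotaxis, outer membrane porins, and genes deleted in BW25113. Of the 212 tests, 88 passed, 38 up and 50 down, and 33 passed with the correlation of each list estimated from the residuals.

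The genes named were set by a rule fixed before the data were examined. It takes *ppsA*, every gene of the gluconeogenesis, acetate and BW25113 deletion lists, up to 4 members with the smallest adjusted p of every other list in each contrast, and the 8 largest rises and 8 largest falls per contrast among genes past the test whose replicates lie on 1 side of 0, or, for a strain difference, do not overlap at any time point. Genes outside this rule appear only in the closing part and are said to be chosen after their values were seen.

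Wild-type and mutant samples share replicate numbers. At 1 to 4 h the deviations of same-numbered samples from their group means correlated across genes at r = 0.195 to 0.376 in all 8 pairs. The wild type has 2 replicates in the fit at each of these times, whose deviations mirror each other, so the 8 pairs are not independent. The number there goes with the print layout and the dye, so that the pairing may be no more than a shared layout. The fit described above holds no term for this pairing, so its strain differences are unpaired. Fits with the replicate number as a block or the print layout as a term stand beside the strain differences where they change a call or move a count by more than 1.5 times. Samples of 1 strain and 1 replicate number also varied together over time while they stayed on 1 print layout, with r = 0.203 to 0.816 between deviations at neighbouring times. Where the layout changed, r was -0.021 (wild-type replicate 1, 30 min to 1 h) and -0.083 (mutant replicate 1, 4 to 5 h), so the number alone does not tie samples. The random block correlation was 0.513 for strain and print layout and 0.484 for strain and replicate number, so p-values of the fit without a block are likely too small. Whether replicate numbers stand for cultures, and whether a reference sample was shared between arrays, is not given in the sources used here.

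The steps were tested on simulated data with the real design, missing values and spread, with 200 changed genes. The simulated samples varied independently, without the correlation within strain and replicate number or print layout described above. The shares that follow hold for independent samples only and do not show how many of the real calls are false. For the wild-type middle phase (3043 genes), 19.4% of genes changed by 0.1 units were called, 83.6% of those changed by 0.3 and 100% of those changed by 0.6; 10.8% of the calls were unchanged genes, and 11 of these 21 genes had no dye term. For the middle strain difference (3012 genes) the shares were 0%, 38.8% and 90.9%, with 4.3% of calls unchanged, and for the late one (1736 genes) 7.5%, 73.1% and 93.9%, with 2.8%. Alternatives fixed beforehand were uncentred or scaled slides, no dye term, Cy3 replicates alone, the replicate block, a random block of strain and replicate number, the layout term, genes measured in every replicate, medians over spots, a size minimum of 1 unit, the estimated correlation and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.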

Results

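Relative transcript levels were measured in *Escherichia coli* BW25113, a K-12 strain, and in a *ppsA* mutant after a move from glucose to acetate minimal medium. *ppsA* encodes phosphoenolpyruvate synthase, which makes phosphoenolpyruvate from pyruvate when cells grow on substrates such as lactate or acetate. On each 2-colour array, RNA from 1 time point was compared with RNA of the same strain harvested just before the move. The series holds 81 slides, 43 of the wild type and 38 of the mutant, at 9 time points from 5 min to 6 h. They make up 41 replicates of 18 groups, where a group is 1 strain at 1 time point. A slide gave values for 900 to 2803 of the 3196 named genes, with a median of 1956. Gene comparisons rest on 35 replicates, 16 of the wild type and 19 of the mutant, and their number limits the precision. The wild type had 2 replicates at each time up to 4 h and 1 at 5 and 6 h. The mutant had 1 replicate at 5, 15 and 30 min, 3 at 1 to 4 h and 2 at 5 and 6 h.

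Values are log ratios in the deposited log units, positive where the transcript was higher than before the shift. The base of the logarithm is not given in the sources used here, so a value of 0.5 stands for a ratio of 1.41 in base 2, 1.65 in base e or 3.16 in base 10. Errors are standard errors of the fitted phase mean, and n is the number of replicates behind it, summed over the time points of the phase. Replicates of 1 number at neighbouring times varied together while they stayed on 1 print layout. The n is therefore not a number of independent samples. Errors and p-values of the main fit, which holds no block, are likely too small. For a strain difference, n gives the mutant and then the wild-type replicates. The p-values, from limma, measure only the spread between these samples. In the mutant at 5, 15 and 30 min each group holds 1 sample, so these samples give no spread of their own. Errors and p-values of the mutant there, and its part in the early strain difference, rest on the spread of the other groups.

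The targeted gene, *ppsA* (b1702), fell in the wild type over the first 30 min, to -0.43 ± 0.06 (SE, n = 6) with an adjusted p of 2.77e-05, and was below 0 in all 6 replicates. At 1 and 2 h its mean was -0.06 ± 0.06 (adjusted p = 0.362), over values of -0.195 and -0.402 at 1 h and of 0.213 and 0.131 at 2 h, and at 3 to 6 h it rose to 0.43 ± 0.05 (SE, n = 6) with an adjusted p of 2.08e-05. Without wild-type replicate 1, which leaves 1 sample each at 3 and 4 h and none later, the late mean was 0.234 and no longer passed the test. In the mutant, the *ppsA* spots gave a value in 6 of 19 replicates, between -0.07 and 0.33, and at too few time points for the phases used here. A test at 3 and 4 h alone, added after the values were seen, gave a mutant mean of 0.05 ± 0.06 (SE, n = 4, adjusted p = 0.51) and a difference from the wild type of -0.34 ± 0.08 (SE, n = 4 and 4, adjusted p = 0.0131). Whether these spots lie within the altered part of the gene is not given in the sources used here, so they do not check the strain labels. The *araBAD*, *rhaBAD* and *lacZ* genes, which BW25113 lacks in whole or in part, gave 113 values between -0.44 and 0.49, with a median of 0.13. In the 6 responses described below, 10 of 22 tests of these genes passed an adjusted p of 0.05, with changes of up to 0.33. Changes of that size thus also occurred at spots whose gene is absent or incomplete. Of all genes tested, between 49.1% and 58.8% passed in these responses, a share not far above that of these genes. A call alone may thus not reflect the transcript of the named gene.

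**Figure D1:**
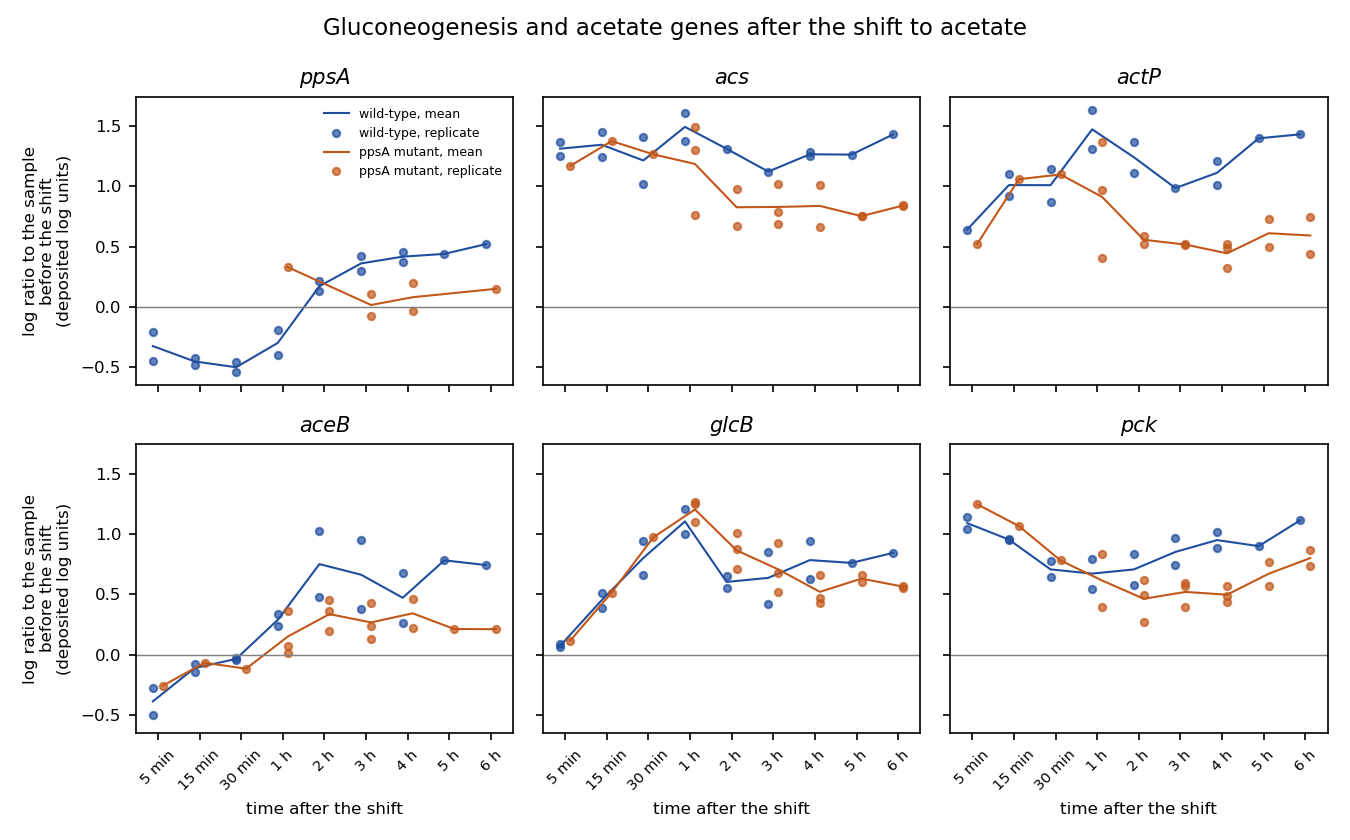
Log ratio of 6 genes to the sample before the shift (deposited log units, vertical axis) against time after the shift (9 time points at equal spacing, horizontal axis). Points are replicates and lines join the means of the wild type (blue) and the *ppsA* mutant (orange); in the late phase *ppsA* averaged 0.43 in the wild type, and *acs* averaged 1.31 in the wild type and 0.83 in the mutant.

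The first comparison asked which transcripts changed within 30 min of the shift in the wild type. The transcript of *acs*, which encodes acetyl-CoA synthetase, rose by 1.34 ± 0.09 (SE, n = 6), and that of *pck*, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose by 0.89 ± 0.06 (SE, n = 6). The largest rise was that of *ytfQ*, the binding protein of a galactofuranose transporter, at 1.80 ± 0.12 (SE, n = 6). Among the largest falls were *lysC*, which encodes an aspartate kinase of lysine synthesis, at -1.42 ± 0.11 (SE, n = 5), *entC* of enterobactin synthesis, at -1.19 ± 0.09 (SE, n = 6), and *icd*, which encodes isocitrate dehydrogenase, at -1.12 ± 0.08 (SE, n = 6).

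Of the genes for uptake and use of other carbon sources that CRP activates, 27 of 35 rose and 1 fell (median 0.41, adjusted p = 1.34e-15). *glpK* stood at 1.03, *glpF* at 0.95 and *araF* at 0.82. For fatty acid degradation 5 of 6 rose (median 0.90, adjusted p = 5.71e-08). *fadD* stood at 1.41 and *fadB* at 1.21. In PTS sugar uptake 8 of 12 rose and 2 fell (median 0.40, adjusted p = 0.00107, and adjusted p = 0.0638 with an estimated correlation). *fruA* stood at 0.51. Of the genes that depend on RpoS, the general stress sigma factor, 24 of 36 rose and 1 fell (median 0.33, adjusted p = 7.51e-07, and adjusted p = 0.109 with an estimated correlation). *dps* stood at 0.78 and *yeaG* at 0.63. Ribosomal protein genes fell in 37 of 48 cases and rose in 1 (median -0.39, adjusted p = 3.75e-12). *rplB* stood at -0.75 and *rpsK* at -0.60. Genes of translation factors and RNA polymerase fell in 14 of 15 cases (median -0.24, adjusted p = 1.22e-05). *rpoA* stood at -0.85. Aminoacyl-tRNA synthetase genes fell in 15 of 18 (median -0.30, adjusted p = 9.21e-07, and adjusted p = 0.0619 with an estimated correlation). Amino acid biosynthesis genes fell in 42 of 66 cases and rose in 10 (median -0.29, adjusted p = 4.35e-07). *aroG* stood at -0.81 and *dapA* at -0.58. Purine and pyrimidine genes fell in 19 of 21 cases (median -0.36, adjusted p = 3.90e-09). *guaB* stood at -0.98. Iron acquisition genes fell in 16 of 21 cases and rose in 1 (median -0.53, adjusted p = 4.38e-07). *fhuF* stood at -0.70. ATP synthase genes fell in 6 of 7 cases (median -0.38, adjusted p = 0.00909, and adjusted p = 0.308 with an estimated correlation). *atpA* stood at -0.64.

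Of the outer membrane porin genes 5 of 6 fell and 1 rose. *lamB*, the maltose porin, stood at 1.18 and *ompT*, an outer membrane protease, at -1.26. The list as a whole passed under the replicate block (adjusted p = 0.0195) but not in the main fit (median -0.56, adjusted p = 0.126). The pentose phosphate and Entner-Doudoroff genes did not pass, with 6 of 9 that fell and 1 that rose (median -0.22, adjusted p = 0.0801). Nor did the lists that hold *acs* and *pck*. Acetate uptake and glyoxylate shunt genes rose in 3 of 8 cases (median 0.08, adjusted p = 0.0513, and 0.00718 under the replicate block). Of the 5 gluconeogenesis genes 1 rose and 1 fell (median 0.06, adjusted p = 0.316). Adjusted over the list alone, the numbers that rose and fell were 29 and 1 for the CRP-activated genes, 1 and 37 for ribosomal proteins, 10 and 45 for amino acid biosynthesis, 0 and 19 for purines and pyrimidines, 0 and 16 for aminoacyl-tRNA synthetases and 1 and 16 for iron acquisition. In total, 1493 of 2841 genes changed at an adjusted p under 0.05, 651 up and 842 down. Without wild-type replicate 1 the number was 710 of 2348 genes tested, and without wild-type replicate 2 it was 931 of 2560.

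In the mutant over the first 30 min, *acs* rose by 1.32 ± 0.12 (SE, n = 3) and *pck* by 1.00 ± 0.08 (SE, n = 3). Their lists did not pass in the main fit, with medians of 0.186 for acetate uptake and glyoxylate shunt and 0.115 for gluconeogenesis. The largest rises were those of *ytfQ* at 1.71 ± 0.15 (SE, n = 3) and *mocA* at 1.69 ± 0.12 (SE, n = 3). Large falls were seen for *thrA*, which encodes the first enzyme of threonine synthesis, at -1.46 ± 0.15 (SE, n = 3), *leuA* of leucine synthesis, at -1.29 ± 0.10 (SE, n = 3), and *ilvC* of branched-chain amino acid synthesis, at -1.28 ± 0.08 (SE, n = 3). The CRP-activated genes rose in 20 of 26 cases (median 0.50, adjusted p = 8.79e-09). *malK* stood at 1.16. The fatty acid degradation genes rose in 4 of 5 (median 1.04, adjusted p = 3.60e-05, and adjusted p = 0.0622 with an estimated correlation). *fadJ* stood at 1.00. RpoS-dependent genes rose in 19 of 27 cases and fell in 1 (median 0.34, adjusted p = 1.15e-05, and adjusted p = 0.116 with an estimated correlation). Ribosomal protein genes fell in 20 of 26 cases (median -0.44, adjusted p = 3.71e-09). *rplB* stood at -0.95 and *rplQ* at -0.82. Aminoacyl-tRNA synthetase genes fell in 13 of 15 (median -0.39, adjusted p = 1.16e-07). *tyrS* stood at -0.72. Purine and pyrimidine genes fell in 8 of 9 cases (median -0.53, adjusted p = 4.64e-05). *guaA* stood at -1.10. Falls were also found in 26 of 50 amino acid biosynthesis genes, with 7 that rose (median -0.23, adjusted p = 5.85e-05, and adjusted p = 0.0619 with an estimated correlation), and in 6 of 8 iron acquisition genes (median -0.46, adjusted p = 0.0105, and adjusted p = 0.139 with an estimated correlation). They extended to 4 of 4 ATP synthase genes (median -0.62, adjusted p = 0.0135, and adjusted p = 0.215 with an estimated correlation). Translation factor and RNA polymerase genes fell in 9 of 12 cases (median -0.19, adjusted p = 0.00193, and adjusted p = 0.137 with an estimated correlation). With adjustment over the list alone, the numbers that rose and fell were 21 and 1 for the CRP-activated genes, 0 and 21 for ribosomal proteins and 7 and 26 for amino acid biosynthesis. In total, 868 of 1537 genes changed, 428 up and 440 down, with 1 replicate at each of the 3 time points, and 565 with strain and print layout as a random block.

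The next comparison asked how the wild type stood at 1 and 2 h, the middle phase. *acs* stood at 1.43 ± 0.12 (SE, n = 3), *actP*, which encodes an acetate permease, at 1.36 ± 0.10 (SE, n = 4), and *aceB* and *aceA*, which encode malate synthase and isocitrate lyase of the glyoxylate shunt, rose by 0.52 ± 0.09 (SE, n = 4) and 0.69 ± 0.12 (SE, n = 2). With the layout term *aceA* was 0.263, and with the unmatched wild-type replicates included it was -0.007 and did not pass. The latter fit adds values that do not go with their gene names, so it does not bear on *aceA*. Of the acetate uptake and glyoxylate shunt genes, 8 of 9 rose and 0 fell (median 0.69, adjusted p = 1.36e-06). The largest rises were those of *lsrB* and *lsrF*, of autoinducer-2 uptake and processing, at 1.53 ± 0.18 (SE, n = 3) and 1.52 ± 0.08 (SE, n = 3). The largest fall was that of *fepA*, the outer membrane receptor for ferric enterobactin, at -1.60 ± 0.06 (SE, n = 3), followed by *yncE* at -1.50 ± 0.16 (SE, n = 2) and *lysC* at -1.48 ± 0.13 (SE, n = 3).

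Iron acquisition genes fell in 22 of 27 cases (median -0.76, adjusted p = 1.34e-15). *fhuF* stood at -1.07. Ribosomal protein genes fell in 46 of 50 cases (median -0.49, adjusted p = 8.76e-21). *rplB* stood at -0.59 and *rplV* at -0.49. Genes of translation factors and RNA polymerase fell in 14 of 16 (median -0.25, adjusted p = 3.61e-06). Amino acid biosynthesis genes fell in 52 of 71 cases and rose in 10 (median -0.50, adjusted p = 4.92e-11). *ilvC* stood at -1.09. Purine and pyrimidine genes fell in 22 of 24 (median -0.44, adjusted p = 9.39e-09). *guaA* stood at -0.83. Acid resistance genes rose in 9 of 12 cases and fell in 1 (median 0.66, adjusted p = 0.0088, and adjusted p = 0.428 with an estimated correlation). *gadA* stood at 1.13 and *gadX* at 0.66. RpoS-dependent genes rose in 26 of 37 cases (median 0.24, adjusted p = 1.35e-06, and adjusted p = 0.117 with an estimated correlation). *kbp* stood at 0.70. CRP-activated genes rose in 26 of 34 (median 0.38, adjusted p = 1.17e-08, and adjusted p = 0.0553 with an estimated correlation). *dctA*, a dicarboxylate transporter gene, stood at 0.62. All 6 fatty acid degradation genes rose (median 0.66, adjusted p = 0.0014, and adjusted p = 0.207 with an estimated correlation). Fermentation and anaerobic respiration genes rose in 10 of 23 cases and fell in 1 (median 0.15, adjusted p = 0.00609, and adjusted p = 0.115 with an estimated correlation). *frdB* of fumarate reductase stood at 0.61. ATP synthase genes fell in 8 of 8 cases (median -0.49, adjusted p = 0.000123, and adjusted p = 0.148 with an estimated correlation). Aminoacyl-tRNA synthetase genes fell in 20 of 22 (median -0.32, adjusted p = 3.08e-07, and adjusted p = 0.0653 with an estimated correlation). Over the list alone, adjustment gave numbers that rose and fell of 8 and 0 for acetate uptake and glyoxylate shunt, 0 and 22 for iron acquisition, 0 and 46 for ribosomal proteins, 10 and 52 for amino acid biosynthesis, 10 and 1 for acid resistance and 27 and 0 for RpoS-dependent genes. In total, 1546 of 3043 genes changed, 685 up and 861 down. Without wild-type replicate 1 the number was 715 of 1880 genes tested.

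In the mutant at 1 and 2 h, the largest rises were those of *prpC*, *prpD* and *prpB*, which encode enzymes of propionate use, at 1.65 ± 0.14 (SE, n = 2), 1.22 ± 0.07 (SE, n = 4) and 1.18 ± 0.23 (SE, n = 2). *glcB*, which encodes malate synthase G, rose by 1.02 ± 0.06 (SE, n = 6) and *acs* by 1.02 ± 0.09 (SE, n = 5). *metE*, which encodes methionine synthase, fell to -1.42 ± 0.07 (SE, n = 3), *lysC* to -1.40 ± 0.09 (SE, n = 6) and *fepA* to -1.39 ± 0.06 (SE, n = 3). Ribosomal protein genes fell in 51 of 52 cases (median -0.49, adjusted p = 1.39e-30). *rplV* stood at -0.63 and *rplC* at -0.63. Falls were also found in 23 of 24 purine and pyrimidine genes (median -0.43, adjusted p = 4.85e-12). *pyrD* stood at -0.87. Iron acquisition genes fell in 25 of 28 cases (median -0.47, adjusted p = 2.04e-11). *entC* stood at -1.21. Amino acid biosynthesis genes fell in 50 of 73 cases and rose in 15 (median -0.37, adjusted p = 1.17e-08). ATP synthase genes fell in 8 of 8 (median -0.63, adjusted p = 1.26e-08). *atpH* stood at -0.73. Translation factor and RNA polymerase genes fell in 14 of 16 cases (median -0.33, adjusted p = 1.48e-07). Aminoacyl-tRNA synthetase genes fell in 15 of 22 (median -0.19, adjusted p = 0.000558, and adjusted p = 0.253 with an estimated correlation). RpoS-dependent genes rose in 32 of 37 cases (median 0.39, adjusted p = 1.39e-09). *dps* stood at 0.67 and *wrbA* at 0.44. Acetate uptake and glyoxylate shunt genes rose in 7 of 9 cases (median 0.51, adjusted p = 8.30e-05, and adjusted p = 0.0553 with an estimated correlation). The median was 0.34 under the replicate block and 0.296 with the layout term. CRP-activated genes rose in 28 of 37 and fell in 1 (median 0.33, adjusted p = 2.14e-08, and adjusted p = 0.0638 with an estimated correlation). Fermentation and anaerobic respiration genes rose in 15 of 23 and fell in 1 (median 0.16, adjusted p = 0.000977, and adjusted p = 0.052 with an estimated correlation). When adjusted within each list, the numbers that rose and fell were 0 and 51 for ribosomal proteins, 0 and 23 for purines and pyrimidines, 0 and 25 for iron acquisition, 15 and 51 for amino acid biosynthesis and 33 and 0 for RpoS-dependent genes. In total, 1523 of 3099 genes changed, 713 up and 810 down.

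At 3 to 6 h the wild type still had *acs* and *actP* at 1.31 ± 0.10 (SE, n = 5) and 1.28 ± 0.10 (SE, n = 5), and *pck* at 0.94 ± 0.06 (SE, n = 6). *aldA*, which encodes an aldehyde dehydrogenase, rose by 1.20 ± 0.05 (SE, n = 6) and *dctA* by 0.97 ± 0.05 (SE, n = 6). The largest falls were those of *ompX*, an outer membrane protein gene, at -0.96 ± 0.08 (SE, n = 6), *cirA*, a siderophore receptor gene, at -0.91 ± 0.09 (SE, n = 6) and *pliG*, a lysozyme inhibitor gene, at -0.88 ± 0.04 (SE, n = 6). TCA cycle genes rose in 11 of 14 cases and fell in 1 (median 0.49, adjusted p = 8.54e-11). *sucC* stood at 0.87 and *sucA* at 0.56. All 4 measured gluconeogenesis genes rose (median 0.33, adjusted p = 0.000155), *ppsA* and *pck* as given above, *fbp* at 0.22 and *glpX* at 0.19. With the layout term *glpX* was 0.098 and did not pass (adjusted p = 0.0514), nor did it with strain and print layout as a random block (adjusted p = 0.196). Acetate uptake and glyoxylate shunt genes rose in 6 of 7 cases (median 0.70, adjusted p = 1.42e-05). *aceB* stood at 0.70. CRP-activated genes rose in 15 of 25 with 2 that fell (median 0.46, adjusted p = 5.34e-09). *gatC* of galactitol uptake stood at 0.95.

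Oxidative stress genes in the wild type at 3 to 6 h fell in 8 of 13 cases and rose in 2 (median -0.17, adjusted p = 0.0135). *zwf*, which encodes glucose-6-phosphate dehydrogenase, stood at -0.50 and *sufS* of iron-sulfur cluster assembly at -0.30. Glycolysis genes fell in 6 of 10 cases (median -0.18, adjusted p = 0.021, and adjusted p = 0.207 with an estimated correlation). *gapA* stood at -0.39. PTS sugar uptake genes fell in 6 of 9 with 2 that rose (median -0.32, adjusted p = 0.00889, and adjusted p = 0.117 with an estimated correlation). *ptsG*, the glucose transporter gene, stood at -0.47. Iron acquisition genes fell in 12 of 21 cases (median -0.23, adjusted p = 0.000522, and adjusted p = 0.139 with an estimated correlation). Acid resistance genes rose in 7 of 8 cases (median 0.54, adjusted p = 0.00194, and adjusted p = 0.272 with an estimated correlation). *hdeA* stood at 0.85. Aerobic respiratory chain genes rose in 8 of 14 cases and fell in 1 (median 0.26, adjusted p = 0.00276, and adjusted p = 0.207 with an estimated correlation). Heat shock genes rose in 7 of 10 (median 0.17, adjusted p = 0.0297, and adjusted p = 0.296 with an estimated correlation). With the layout term the heat shock list did not pass (median 0.081, adjusted p = 0.0732). *groL* stood at 0.33. Ribosomal protein genes fell in 12 of 31 cases and rose in 2, and the list did not pass (median -0.06, adjusted p = 0.205). Adjusted over the list alone, the numbers that rose and fell were 11 and 1 for the TCA cycle, 4 and 0 for gluconeogenesis, 6 and 0 for acetate uptake and glyoxylate shunt, 1 and 7 for glycolysis and 8 and 0 for acid resistance. In total, 914 of 1795 genes changed, 433 up and 481 down. With strain and print layout as a random block the number was 428. Without wild-type replicate 1, which also takes away 5 and 6 h, it was 441 of 1995 genes tested, and without wild-type replicate 3 it was 534 of 1715.

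In the mutant at 3 to 6 h, *bssR*, a biofilm regulator gene, rose by 1.16 ± 0.04 (SE, n = 7), *cysH* and *cysJ* of sulfate assimilation by 0.99 ± 0.07 (SE, n = 10) and 0.83 ± 0.06 (SE, n = 10), and *aroF* and *tyrA* of tyrosine synthesis by 0.85 ± 0.10 (SE, n = 10) and 0.82 ± 0.12 (SE, n = 10). *acs* stood at 0.83 ± 0.07 (SE, n = 9). *zinT*, a zinc-binding protein gene, fell to -1.43 ± 0.11 (SE, n = 4), *metE* to -1.37 ± 0.06 (SE, n = 5) and *gdhA*, which encodes glutamate dehydrogenase, to -0.99 ± 0.05 (SE, n = 9). TCA cycle genes rose in 13 of 17 cases and fell in 3 (median 0.38, adjusted p = 1.96e-06). *sdhA* stood at 0.73. Acetate uptake and glyoxylate shunt genes rose in 9 of 9 (median 0.40, adjusted p = 0.000127, and adjusted p = 0.0622 with an estimated correlation). Ribosomal protein genes fell in 39 of 43 cases and rose in 1 (median -0.33, adjusted p = 4.85e-12). *rplV* stood at -0.41. Genes of translation factors and RNA polymerase fell in 15 of 16 (median -0.30, adjusted p = 6.66e-09). *tsf* stood at -0.59.

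In 10 further lists of the mutant at 3 to 6 h the call was lost with an estimated correlation. Of the amino acid biosynthesis genes, 38 of 62 fell and 15 rose (median -0.21, adjusted p = 0.000302, and adjusted p = 0.117 with an estimated correlation). *ilvC* stood at -1.03 and *cysI* at 0.75. ATP synthase genes fell in 7 of 7 cases (median -0.41, adjusted p = 0.000111, and adjusted p = 0.117 with an estimated correlation). Iron acquisition genes fell in 14 of 23 (median -0.20, adjusted p = 0.00261, and adjusted p = 0.226 with an estimated correlation). *entC* stood at -0.78. Aminoacyl-tRNA synthetase genes fell in 12 of 21 cases (median -0.14, adjusted p = 0.0221, and adjusted p = 0.428 with an estimated correlation), and with the replicate number as a block their adjusted p was 0.0682. CRP-activated genes rose in 22 of 34 cases and fell in 1 (median 0.24, adjusted p = 2.96e-06, and adjusted p = 0.122 with an estimated correlation). RpoS-dependent genes rose in 20 of 37 and fell in 1 (median 0.15, adjusted p = 0.00184, and adjusted p = 0.328 with an estimated correlation). Aerobic respiratory chain genes rose in 11 of 17 and fell in 3 (median 0.21, adjusted p = 0.00459, and adjusted p = 0.278 with an estimated correlation). Fermentation and anaerobic respiration genes rose in 12 of 18 cases (median 0.13, adjusted p = 0.00315, and adjusted p = 0.0638 with an estimated correlation). Heat shock genes rose in 10 of 16 and fell in 1 (median 0.15, adjusted p = 0.0321, and adjusted p = 0.381 with an estimated correlation). With the layout term the heat shock median was 0.084. *dnaK* stood at 0.46. Flagella and chemotaxis genes rose in 20 of 35 cases and fell in 1 (median 0.12, adjusted p = 0.0216, and adjusted p = 0.296 with an estimated correlation). *flgK* stood at 0.21. Adjusted over the list alone, the numbers that rose and fell in the mutant at 3 to 6 h were 2 and 40 for ribosomal proteins, 0 and 15 for translation factors and RNA polymerase, 13 and 3 for the TCA cycle and 15 and 38 for amino acid biosynthesis. In total, 1582 of 2692 genes changed, 755 up and 827 down.

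**Figure D2:**
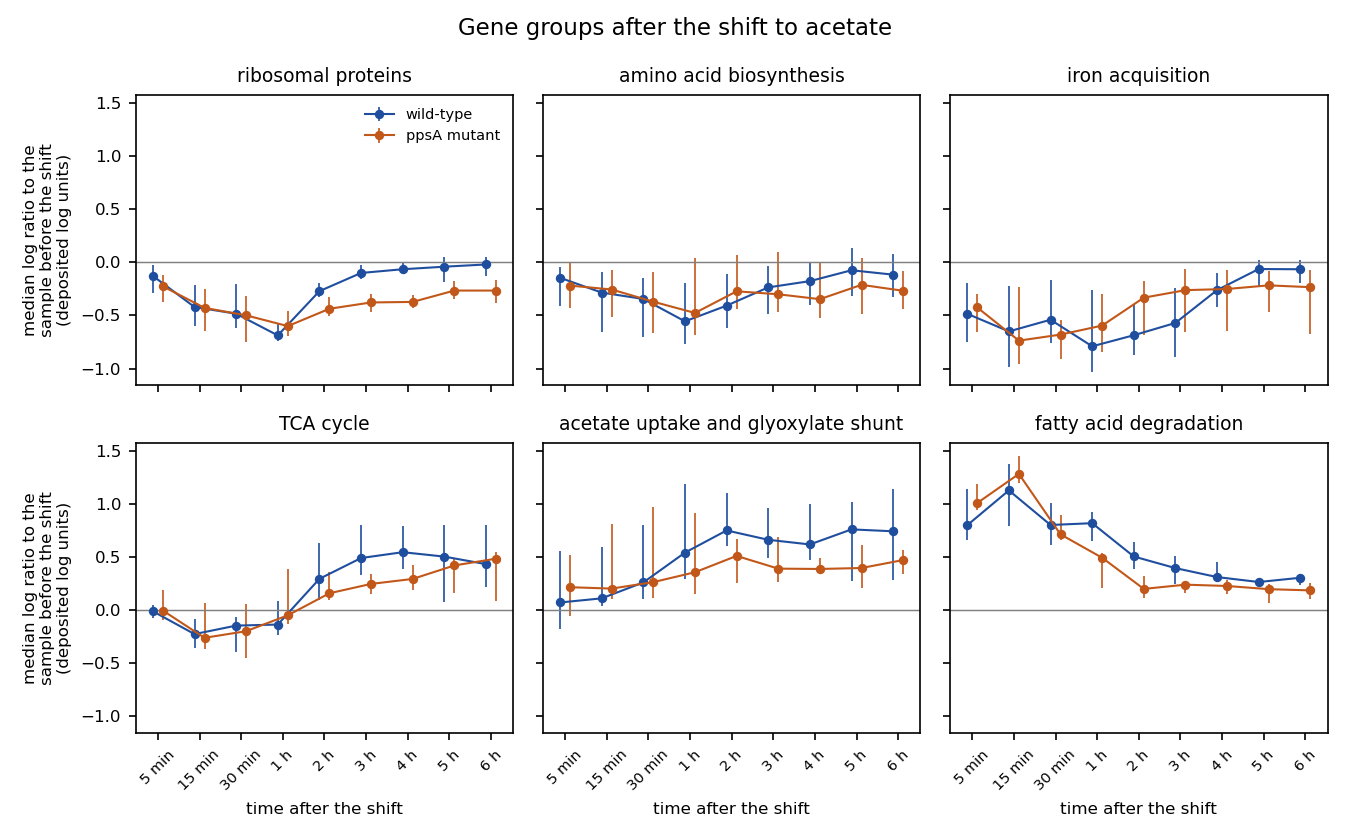
Median log ratio of 6 gene groups to the sample before the shift (deposited log units, vertical axis) against time after the shift (9 time points at equal spacing, horizontal axis). Points are medians over the measured genes of a group and bars span the quartiles over these genes, for the wild type (blue) and the *ppsA* mutant (orange); ribosomal protein genes stood at -0.02 in the wild type and -0.265 in the mutant at 6 h.

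The last 3 comparisons asked where the mutant and the wild type responded differently to the shift. Each strain was compared with its own sample before the shift, so higher or lower in the mutant refers to these responses. No array compared the strains directly, so their transcript levels were not compared. Over the first 30 min, few single genes differed. *malK* of maltose uptake was higher in the mutant by 0.55 ± 0.12 (SE, n = 3 and 6) and *yjdJ* by 0.27 ± 0.06 (SE, n = 3 and 6), and *pspB*, of the phage shock operon, and *fmt*, which encodes methionyl-tRNA formyltransferase, were lower, at -0.52 ± 0.09 (SE, n = 3 and 6) and -0.27 ± 0.05 (SE, n = 3 and 6). In total, 6 of 1526 genes differed with limma, 2 higher and 4 lower in the mutant, and 143 had an unadjusted p under 0.05. Of the preset lists, ribosomal protein genes (median -0.08, adjusted p = 0.000111, and adjusted p = 0.148 with an estimated correlation) and amino acid biosynthesis (median -0.06, adjusted p = 0.021, and adjusted p = 0.301 with an estimated correlation) were lower in the mutant. So were iron acquisition (median -0.09, adjusted p = 0.0263, and adjusted p = 0.207 with an estimated correlation) and purine and pyrimidine genes (median -0.15, adjusted p = 0.00738, and adjusted p = 0.117 with an estimated correlation). RpoS-dependent genes were higher as a list (median 0.07, adjusted p = 0.00243, and adjusted p = 0.296 with an estimated correlation). The median of each of these 5 lists changed sign when slides were scaled to the same spread. No member of these lists differed by the test over all genes, and adjusted over the list alone 4 ribosomal protein genes were lower and 2 RpoS-dependent genes higher. With strain and replicate number as a random block the ribosomal protein genes (median -0.019, adjusted p = 0.349), RpoS-dependent genes (median 0.022, adjusted p = 0.415) and amino acid biosynthesis (adjusted p = 0.102) did not pass. Under that fit porins (adjusted p = 0.0173), flagella and chemotaxis (adjusted p = 0.0301) and heat shock (adjusted p = 0.00276) did, and the median for iron acquisition was -0.195. With the replicate number as a block 10 genes differed, with the print layout as a term 45, and with strain and replicate number as a random block 2, or with strain and print layout 0. Under the replicate block *malK*, *yjdJ*, *pspB* and *fmt* did not pass (adjusted p = 0.0775, 0.0509, 0.0562 and 0.0509), nor did they under either random block. The lists of amino acid biosynthesis (adjusted p = 0.275) and iron acquisition (adjusted p = 0.236) did not pass under the replicate block, while heat shock did (adjusted p = 0.004, against 0.185). The CRP-activated genes passed with the layout term (adjusted p = 0.0337, against 0.0513). All early samples are on layout D, so the layout term leaves the early differences as they are. It acts on their calls only through the shared spread. The count was 0 without wild-type replicate 1, 1 without wild-type replicate 2, 24 without mutant replicate 2 and 12 without mutant replicate 3; these 2 mutant replicates hold no early sample and act only through the shared spread and dye term. With slides scaled to the same spread it was 17, of which 11 were higher.

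At 1 and 2 h, *trpE*, *trpD*, *trpB* and *trpA*, of the tryptophan operon, were higher in the mutant by 1.58 ± 0.19 (SE, n = 4 and 2), 1.33 ± 0.19 (SE, n = 3 and 2), 1.33 ± 0.14 (SE, n = 3 and 2) and 1.05 ± 0.18 (SE, n = 4 and 2), and *tyrA* and *aroF*, of tyrosine synthesis, by 1.10 ± 0.27 (SE, n = 6 and 3) and 1.04 ± 0.20 (SE, n = 6 and 4). In the wild type *trpE* averaged -0.65 and in the mutant 0.93. The 2 wild-type values behind each *trp* gene are 1 at 1 h and 1 at 2 h. For most of these genes both come from wild-type replicate 1, whose samples at these times varied together (r = 0.68). *nrdH* and *nrdI*, of the ribonucleotide reductase operon, were higher by 0.68 ± 0.10 (SE, n = 4 and 2) and 0.66 ± 0.13 (SE, n = 3 and 2). *lsrF* was lower by 0.71 ± 0.11 (SE, n = 3 and 3) and *actP* by 0.61 ± 0.14 (SE, n = 5 and 4).

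Amino acid biosynthesis genes were higher in the mutant in 13 of 71 cases and lower in 1 (median 0.02, adjusted p = 0.00549, and adjusted p = 0.271 with an estimated correlation). *aroH* differed by 0.58 and *aroG* at 0.41 beside those named above. Within print layouts the median was 0.05 in layout A and 0.07 in layout C. Iron acquisition genes were higher in 4 of 27 cases (median 0.14, adjusted p = 0.00022, and adjusted p = 0.148 with an estimated correlation). *fhuF* differed by 0.61 and *fhuA* at 0.46. The list median was 0.24 in layout A and -0.004 in layout C. Aminoacyl-tRNA synthetase genes were higher in 4 of 22 cases (median 0.10, adjusted p = 0.00143, and adjusted p = 0.291 with an estimated correlation). *pheS* differed by 0.43. For the list the median was 0.09 in layout A and 0.16 in layout C. Oxidative stress genes were higher in 4 of 21 cases (median 0.08, adjusted p = 0.0425, and adjusted p = 0.0708 with an estimated correlation). *trxC* differed by 0.41. The list median was 0.12 in layout A and 0.01 in layout C. Acetate uptake and glyoxylate shunt genes were lower as a list (median -0.25, adjusted p = 0.0263, and adjusted p = 0.301 with an estimated correlation), with *actP* as the 1 member of 9 past the test. By layout, the median was -0.08 in layout A and -0.03 in layout C. Acid resistance genes were also lower as a list (median -0.30, adjusted p = 0.00658, and adjusted p = 0.411 with an estimated correlation), with 1 of 12 past the test, *dctR* at -0.52. The list median was -0.08 in layout A and -0.28 in layout C. Fatty acid degradation genes were lower as a list (median -0.35, adjusted p = 0.00444, and adjusted p = 0.272 with an estimated correlation) with none of 6 past the test. Medians were -0.13 in layout A and -0.01 in layout C. PTS sugar uptake genes were lower as a list with 2 of 11 past the test (median -0.11, adjusted p = 0.0125, and adjusted p = 0.157 with an estimated correlation), *fruB* at -0.33 and *manX* at -0.29. Here the median was -0.05 in layout A and -0.04 in layout C. Flagella and chemotaxis genes were higher as a list (median 0.06, adjusted p = 0.0337, and adjusted p = 0.35 with an estimated correlation) with none of 40 past the test. Their median was 0.14 in layout A and -0.03 in layout C, and the list did not pass under the replicate block (adjusted p = 0.0896) or with the layout term (adjusted p = 0.0904). Outer membrane porin genes, not past the test here (adjusted p = 0.156), passed under the replicate block (adjusted p = 0.0247) and with the layout term (adjusted p = 0.0337). Heat shock genes passed with the layout term (adjusted p = 0.034, against 0.458). With the layout term the medians were -0.157 for acetate uptake and glyoxylate shunt, -0.146 for acid resistance, -0.178 for fatty acid degradation and -0.066 for PTS sugar uptake, and acid resistance stood at -0.18 under the replicate block. Within each list alone, the adjusted numbers higher and lower were 14 and 2 for amino acid biosynthesis, 5 and 0 for iron acquisition, 6 and 0 for aminoacyl-tRNA synthetases, 6 and 1 for oxidative stress and 0 and 3 for fatty acid degradation.

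In total at 1 and 2 h, 165 of 3012 genes differed between the strains, 111 higher and 54 lower in the mutant. Over all genes the differences in the 2 layouts correlated at r = 0.202 across genes, which are not independent replicates. With the replicate number as a block 262 genes differed, with the print layout as a term 346, and with strain and replicate number as a random block 31, or with strain and print layout 30. With strain and replicate number as a random block *tyrA*, *aroF*, *actP* and *nrdI* did not pass (adjusted p = 0.103, 0.0615, 0.0603 and 0.0589), nor did *dctR*, *fruB*, *manX* and *trxC* (adjusted p = 0.0657, 0.085, 0.0666 and 0.172). With strain and print layout instead, *nrdI*, *dctR*, *fruB*, *manX* and *trxC* did not pass (adjusted p = 0.0758, 0.0887, 0.13, 0.0943 and 0.218). The count was 70 without wild-type replicate 2, which holds no sample at 1 and 2 h in the fit and acts only through the shared spread and dye term. It was 73 without wild-type replicate 1, 92 without wild-type replicate 3, 471 without mutant replicate 1 and 259 without mutant replicate 2, and 60 with slides scaled to the same spread.

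At 3 to 6 h, *tyrA* and *aroF* were higher in the mutant by 1.49 ± 0.20 (SE, n = 10 and 6) and 1.29 ± 0.17 (SE, n = 10 and 6), *ompX* by 0.76 ± 0.10 (SE, n = 10 and 6) and *osmE*, an osmotically induced lipoprotein gene, by 0.69 ± 0.07 (SE, n = 8 and 4). *ompW*, an outer membrane protein gene, was lower by 0.94 ± 0.15 (SE, n = 4 and 4), *ilvC* by 0.84 ± 0.08 (SE, n = 8 and 6) and *pyrD* of pyrimidine synthesis by 0.64 ± 0.06 (SE, n = 8 and 6). Also lower in the mutant were *actP* by 0.74 ± 0.12 (SE, n = 9 and 5), *acs* by 0.48 ± 0.11 (SE, n = 9 and 5), *aceB* by 0.45 ± 0.11 (SE, n = 7 and 6) and *pck* by 0.32 ± 0.07 (SE, n = 10 and 6), while *pta*, which encodes phosphotransacetylase, was higher by 0.35 ± 0.09 (SE, n = 8 and 6). For *pta* the difference was 0.183 under the replicate block and 0.177 with the layout term, and for *ompW* it was -0.34 with the layout term. With the unmatched wild-type replicates included *pck* stood at 0.121 and did not pass. That fit adds values that do not go with their gene names, so it does not bear on *pck*.

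Ribosomal protein genes were lower in the mutant in 20 of 29 cases and higher in 0 (median -0.27, adjusted p = 1.56e-08). *rplV* differed by -0.42, *rpsS* at -0.43 and *rplC* at -0.34. Within print layouts the median was -0.38 in layout A and -0.20 in layout C. Layout A holds no sample after 4 h, so these medians, and those of the lists below, are for 3 and 4 h alone. With an estimated correlation the adjusted p of the ribosomal protein list was 0.0373. All 6 measured ATP synthase genes were lower (median -0.33, adjusted p = 0.003, and adjusted p = 0.211 with an estimated correlation). *atpH* differed by -0.44. The median of the list was -0.51 in layout A and -0.14 in layout C. Genes of translation factors and RNA polymerase were lower in 9 of 12 cases (median -0.18, adjusted p = 0.00041, and adjusted p = 0.0852 with an estimated correlation). *tufA* differed by -0.43. For this list the median was -0.22 in layout A and -0.14 in layout C. TCA cycle genes were lower in 6 of 14 cases (median -0.20, adjusted p = 0.0244, and adjusted p = 0.296 with an estimated correlation). *sucC* differed by -0.49. Its list had a median of -0.28 in layout A and -0.15 in layout C. This list did not pass under the replicate block (adjusted p = 0.0573), with the layout term (adjusted p = 0.0594) or with strain and replicate number as a random block (adjusted p = 0.0541). Of the gluconeogenesis genes 3 of 3 were lower and the list did not pass (median -0.18, adjusted p = 0.109). Neither did the acetate uptake and glyoxylate shunt genes, 3 of 7 lower and 1 higher (median -0.13, adjusted p = 0.28). Adjusted over the list alone, the numbers higher and lower were 0 and 20 for ribosomal proteins, 0 and 6 for ATP synthase, 0 and 10 for translation factors and RNA polymerase and 0 and 7 for the TCA cycle.

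In total at 3 to 6 h, 680 of 1736 genes differed, 340 higher and 340 lower in the mutant. Between layouts A and C the differences over all genes at 3 and 4 h correlated at r = 0.434 across genes. Of the genes that differed, 533 of 626 had the same sign in layout A and 573 of 581 in layout C. The samples of these layouts are also behind the calls. With strain and print layout as a random block 237 genes differed, with strain and replicate number 380, and with 3 and 4 h alone 418 of 3054. Under the first of these *aceB*, *acs* and *pta* did not pass (adjusted p = 0.114, 0.0552 and 0.114), and *ompW* did not with the layout term (adjusted p = 0.16). The count was 437 of 1661 genes without wild-type replicate 3. It was 128 of 1991 without wild-type replicate 1, which also takes away 5 and 6 h and leaves 1 wild-type sample each at 3 and 4 h.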

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

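Chosen only after the result was seen were the test of other TyrR and TrpR targets, the margin of the reference sample test, the tests of the wild-type slides without usable gene names that concern their signal, other gene tables and shifted spots and the replicate block and layout values for lists. At 1 and 2 h the response of the *ppsA* mutant differed from that of the wild type in 165 of 3012 genes tested. At 3 to 6 h it differed in 680 of 1736, and in the first 30 min in 6 of 1526. The phases differ in the replicates and genes they hold, and the early mutant has 1 replicate at each time. The counts therefore do not show how the strain difference grew over time.

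The genes *trpA*, *trpB*, *trpD*, *trpE*, *tyrA*, *aroF* and *aroH* stood higher in the mutant at 1 and 2 h. Within print layouts, where both strains share the layout, the median difference was 1.369 over 6 genes in layout A and 0.897 over 3 in layout C. For the genes measured there, the difference was thus not confined to a comparison across layouts. These genes were chosen for their difference in the same samples. That they exceed random gene sets (95% below 0.114 and 0.218) was therefore likely in advance and carries no weight. Among the Cy3 replicates, where both strains carry the same dye, the median was 1.195 over 6 genes. For these genes the difference thus did not need both dyes. The wild type there is replicate 1 on layout A alone, so this largely repeats the comparison in layout A. The random sets (95% below 0.116) carry no weight here either, since the genes were chosen for this difference. A low level of these transcripts in a mutant reference sample shared by all times would give the difference at every time. In the first 30 min the median difference was 0.126, with no gene above 0.301 and standard errors of up to 0.254. For the same 6 genes it was 1.214 at 1 and 2 h. With a margin of 1 spread, chosen after the value was seen, it stayed under the bound of 0.607. With the margin first set, 2 times the largest standard error, it did not, so this explanation is not excluded. A separate reference for the later slides was not tested. Release of genes repressed by TyrR and TrpR may account for the pattern, since 10 other targets of these repressors, a set chosen after the values were seen, had a median difference of 0.258, above 95% of random sets (0.085), though only 4 were higher and 1 lower by the test, and at 3 to 6 h their difference did not pass (median 0.212 over 6 genes, adjusted p = 0.29); an effect of the mutation on the supply of phosphoenolpyruvate, a precursor of aromatic amino acids, was not tested.

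Relative to each strain's own sample before the shift, ribosomal protein genes were lower in the mutant at 3 to 6 h, with a median difference of -0.273. Within print layouts the median at 3 and 4 h was -0.393 over 49 genes in layout A and -0.162 over 26 in layout C. For the genes measured there, the difference was thus not confined to a comparison across layouts. Each layout held 1 replicate of each strain at each of these times. The list was flagged for its difference in the same samples. That it lay below random lists (5% below -0.046 and -0.081) was therefore likely in advance and carries no weight. The single wild-type replicate at 5 and 6 h is argued against by a median of -0.246 over 49 genes with 3 and 4 h alone (adjusted p = 2.81e-17). Scaling of the slides left the median at -0.275 (adjusted p = 1.82e-09). A slower recovery of growth in the mutant could give such a difference, but no growth measurement was analysed here and this was not tested. Nor was a high level of these transcripts in the mutant's reference sample tested.

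The 11 wild-type slides on layout B whose values do not go with the gene names were singled out because they carry a signal that no comparison used: the 2 slides of a replicate correlated across spots at a median r of 0.885, which argues against values without signal. No other gene table brought them into place, with a highest median r of 0.0493 in size under the other 3 tables, nor did a shift of the spots by any fixed number up to 4332, with at most 0.131. The 2 spots listed for the same gene correlated at a median of 0.889 within a slide, so spot pairs printed for other genes remain a possible explanation. Spots without a gene name on the slides in general also gave a signal that no comparison used, with a median r of 0.9 between the 2 slides of a replicate.

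Whether any grouping of the samples gives such counts was tested by refitting with samples exchanged between the strains within each time point. In the first 30 min the real grouping, with 6 genes, ranked highest, 1 of 27 groupings, and the next gave 3. For 1 and 2 h it was 1 of 100 groupings, with 165 genes against 84 for the next, and at 3 to 6 h 1 of 100 drawn out of 900, with 680 against 619. Each count thus exceeds that of every other grouping tried. The runner-up at 1 and 2 h sets mutant replicates 1 and 2 against all other samples, and the runner-up at 3 to 6 h sets mutant replicates 2 and 3 against the rest, so these groupings follow the replicate number and the layout and point to a structure of the samples. Among groupings that part as many same-numbered pairs as the real one, the next highest counts were 41 genes at 1 and 2 h and 343 at 3 to 6 h. These comparisons hold only 16 and 9 groupings, the real one included, too few for a rank to carry much weight. Samples of 1 strain and number also varied together over time, so single samples are not freely exchangeable and the ranks are not p-values. With strain and replicate number as a random block the 3 counts were 2, 31 and 380, and with strain and print layout 0, 30 and 237.

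Further lists differed between the strains by the test with a preset correlation, and each lost its call with an estimated one, as given in the report. In the first 30 min these were amino acid biosynthesis (median -0.055), iron acquisition (-0.091), purine and pyrimidine biosynthesis (-0.148), ribosomal proteins (-0.082) and RpoS-dependent general stress (0.075), each with the opposite sign under scaled slides. In the middle phase they were acetate uptake and glyoxylate shunt (-0.253), acid resistance (-0.3), amino acid biosynthesis (0.021), aminoacyl-tRNA synthetases (0.1), fatty acid degradation (-0.355), flagella and chemotaxis (0.056), iron acquisition (0.143), oxidative stress defence (0.076) and PTS sugar uptake (-0.114). In the late phase they were ATP synthase (-0.329), the TCA cycle (-0.199) and translation factors and RNA polymerase core (-0.181).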

How the results depend on the processing

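Chosen after the data were seen were the inclusion of the unmatched wild-type replicates, the random block of strain and print layout, the size minimum of a 2-fold change in base 10, the late phase from 3 and 4 h only, the left-out slide of wild-type 5 min replicate 1, the random and replicate blocks and the layout term for lists, and *ppsA* at 3 and 4 h. Contrasts are given in the order wild-type early, mutant early, wild-type middle, mutant middle, wild-type late, mutant late, then early, middle and late strain difference. Counts of genes stayed within 1.5 times those of the report with values as deposited, medians over spots, the left-out slide and the unmatched replicates. The last of these adds values that do not go with their gene names, so it is no check of the counts. Over all alternatives, 1544 list values stayed on their side of the test, 62 newly passed it, 81 no longer did and 9 turned the direction of the test; of 2665 values of named genes, 2541 stayed, 122 no longer passed and 2 changed sign. Signal over background was not analysed here, so what it limits is unknown.

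A size of at least 1 unit left 30, 32, 35, 20, 5, 5, 0, 6 and 2 genes, and a 2-fold change if the base is 10 left 541, 440, 642, 559, 254, 366, 3, 88 and 232, since fewer genes can pass. Scaled slides gave 17 genes for the early difference and 60 for the middle one. Without a dye term the middle difference had 107. With Cy3 replicates only and no dye term, wild-type late had 608, mutant late 953, the early difference 1 and the late one 374, with fewer samples. All early samples are in Cy3, so the early difference lost none of them and moved only through the shared spread. Genes measured in every replicate gave 1006 for wild-type middle, 620 for mutant middle, 501 for mutant late, 98 for the middle difference and 288 for the late one, with fewer genes tested. The replicate block gave 10 genes for the early difference and 262 for the middle one, and moved no other count by more than 1.5 times; among lists it ended 5 calls and added 9. The layout term gave 45 and 346 for the same differences. All early samples are on layout D, so the first of these counts moved only through the shared spread. The random block of strain and replicate number gave 2, 31 and 380 genes for the 3 differences, and that of strain and layout 0, 30 and 237, with 565 for mutant early and 428 for wild-type late. With 3 and 4 h only, the late difference had 418 genes. Other causes were not tested.

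Leaving out 1 replicate number of 1 strain at a time gave 710 to 1754 genes for wild-type early, 720 to 1001 for mutant early, 715 to 1816 for wild-type middle, 1233 to 1597 for mutant middle, 441 to 1098 for wild-type late, 1132 to 1607 for mutant late, and 0 to 24, 70 to 471 and 128 to 674 for the early, middle and late difference. Mutant replicates 2 and 3 hold no early sample, and wild-type replicate 2 none in the fit after 30 min, so there they act only through the shared spread and the dye term. Without mutant replicate 1 the mutant has no early sample, so its early values could not be had. Leaving out wild-type replicate 1 also takes away the wild type's 5 and 6 h, so late values then rest on 3 and 4 h. Where 1 sample of a group was left, it was taken to vary like the other groups. *ppsA* ran from -0.489 to -0.324 in wild-type early, from -0.237 to 0.111 in wild-type middle and from 0.234 to 0.564 in wild-type late, where 0.234, without wild-type replicate 1, was no longer past the test.

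With an estimated correlation, 33 of the 88 list calls held. Under the random block of strain and replicate number, list differences lost, and those gained early, are given in the report. Gained later, by adjusted p, were middle ATP synthase (0.0195) and CRP-activated genes (0.043), and late acid resistance (0.0121). Under scaled slides the early difference of 7 lists changed sign: amino acid biosynthesis 0.069, aminoacyl-tRNA synthetases 0.098, CRP-activated genes -0.135, iron acquisition 0.024, purine and pyrimidine biosynthesis 0.047, ribosomal proteins 0.067 and RpoS-dependent genes -0.031. For fatty acid degradation the direction of the test turned, while the median went from -0.014 to -0.368. With 3 and 4 h only, the late difference of iron acquisition turned to 0.071. With the unmatched replicates included, *aceA* in wild-type middle was -0.007 and *pck* in the late difference 0.121, both of the other sign and not past the test. That fit adds values that do not go with their gene names, so it does not bear on either gene. The cause of the other changes was not tested.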

Other observations

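All gene sets of this part were chosen after their values were seen, and their tests with limma's cameraPR, adjusted over the sets and contrasts of this part alone, are a description of the same data. The *ast* genes of arginine catabolism rose in all 5 measured cases in the wild type over the first 30 min, with a median of 0.976 (adjusted p = 1.55e-11), among them *astA* at 1.38 ± 0.07 (SE, n = 6) and *astC* at 1.37 ± 0.06 (SE, n = 6). At 1 and 2 h their median was 1.047 in the wild type (5 of 5 rose) and 0.855 in the mutant (4 of 4 rose), and the strains differed in none of 4. The *lsr* genes of autoinducer-2 uptake rose at 1 and 2 h in 7 of 7 cases in each strain, with medians of 0.811 and 0.738. Genes of putrescine catabolism and the *ydc* transporter rose in 8 of 8 cases in the wild type at 1 and 2 h (median 0.881, adjusted p = 8.34e-05, and adjusted p = 0.0543 with an estimated correlation) and in 6 of 8 in the mutant (median 0.366, adjusted p = 0.0216, and adjusted p = 0.291 with an estimated correlation). Their median difference was -0.452 (adjusted p = 0.000346, and adjusted p = 0.0844 with an estimated correlation), with 1 of 8 past the test, *ydcT* at -0.46 ± 0.12 (SE, n = 4 and 4).

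The *prp* genes of propionate use rose in the mutant at 1 and 2 h in 4 of 4 cases (median 1.204, adjusted p = 0.0003) and in the wild type in 3 of 4 (median 0.71, adjusted p = 0.0143, and adjusted p = 0.0829 with an estimated correlation). Between the strains 1 of 4 differed, *prpD* at 0.46 ± 0.11 (SE, n = 4 and 3). With strain and replicate number as a random block neither *prpD* (adjusted p = 0.106) nor *ydcT* (adjusted p = 0.19) passed. For *ydcT* the same held without wild-type replicate 1 or 3 and without mutant replicate 2 or 3. Sulfate assimilation genes rose in the mutant at 3 to 6 h in 10 of 11 cases (median 0.579, adjusted p = 2.33e-09, and adjusted p = 0.0594 with an estimated correlation), with *cysH* at 0.99, and in the wild type in 9 of 11 (median 0.44, adjusted p = 0.000485, and adjusted p = 0.291 with an estimated correlation). Between the strains 4 of 11 differed, where 39.2% of all genes did. The difference of the set did not pass (median 0.144, adjusted p = 0.0552, and adjusted p = 0.538 with an estimated correlation). The *nrdHIEF* genes fell in 4 of 4 cases in the wild type at 1 and 2 h (median -0.791, adjusted p = 0.0023, and adjusted p = 0.107 with an estimated correlation). Their median difference between the strains was 0.573, with 3 of 4 higher in the mutant (adjusted p = 0.000145, and 0.0408 with an estimated correlation). Genes of glycolate and glyoxylate use rose in 6 of 6 cases in each strain at 1 and 2 h, with medians of 0.416 in the wild type and 0.677 in the mutant, and none of 5 differed.

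Other genes of the aromatic pathway, outside the group that stood higher in the mutant and outside the TyrR and TrpR targets, fell in the wild type at 1 and 2 h in 4 of 6 cases (median -0.344) and in the mutant in 4 of 6 (median -0.157). Between the strains 2 of 6 were higher in the mutant, with a median difference of 0.099 (adjusted p = 0.0969).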
